A study of Mus musculus with 5 samples.

How the data were processed

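Small RNA was sequenced from NIH 3T12 cells, a line of mouse embryonic fibroblasts, after infection with murine gammaherpesvirus 68 (MHV68) in 3 libraries and after mock treatment in 2. Per the labels' protocols, cells were infected at a multiplicity of 10 plaque-forming units and RNA was taken 18 h later. Libraries were made from 20 µg of total RNA cut from a 15% acrylamide gel at 18 to 30 nt, following version 1.5 of the Illumina small RNA guide. The labels name both the fibroblast line and bone marrow-derived macrophages as the source of each sample, and the series design names the fibroblast line only. Groups and replicate numbers were taken from the sample titles.

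The authors deposited for each library a list of distinct sequence tags with the raw count of reads of each tag, so the unit of every deposited value is a count. The tags were 17 to 30 nt long. Per the submitters' processing notes the genome build mm9 was used; the tools that trimmed adapters and collapsed reads are not given in the sources used here. Total counts were 1843676, 5694227 and 8526798 for infected replicates 1 to 3 and 5682600 and 6521133 for mock replicates 1 and 2. The count that 0 reads allow, taken as 3 counts, came to 1.63, 0.527 and 0.352 CPM (counts scaled to the library total) in the infected libraries and to 0.528 and 0.460 in the mock libraries. The reads carry no molecular identifiers, so intervals and floors cover counting error only.

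Tags of 18 nt or more were matched to the GENCODE mouse M21 transcripts (GRCm38), whole tag, no mismatch, both strands. For the small RNA transcripts the matching was checked on sampled tags against a plain string search. No genome sequence, MHV68 sequence, mature miRNA positions or nuclear tRNA genes were used. Mouse miRNAs were counted per annotated precursor, with precursors that share their most abundant tag merged into one name (Mir378a/Mir378b/Mir378c). A tag was treated as having no mouse match when it matched no transcript on either strand and no small RNA transcript with up to 1 mismatch, over the whole tag or over its first 18 nt. Tags from unannotated mouse loci, mouse tRNAs and adapters therefore remain among the unmatched tags in both groups. Tags fitting several merged miRNAs were left out, at most 0.0301% of precursor-matched reads in a library. Unmatched tags were grouped into 8326 families around a most abundant tag with at least 5 reads, allowing a start shift of up to 3 nt, an overlap of at least 15 nt and differences in the last 3 nt.

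Sequences of 10 MHV68 miRNAs and 15 lists of mouse miRNAs were written down before the data were examined, as were the tests, the alternatives and the rule for named items, except where a choice is said to have been made later. Of the 190 listed mouse names, 189 matched an annotated gene, older symbols through the RefSeq table. A tag counted for a listed MHV68 miRNA when it began within 2 nt of the listed start and matched it to its 18th nt. Apart from miR-M1-7-5p, 1 listed MHV68 miRNA with reads in infected cells is not reported here, and totals and counts over the list include it. No order of abundance is given for the others. The MHV68 sequences were written from memory and not checked against a database. The one listed as miR-M1-7-5p is the reverse complement of the one listed as miR-M1-1, so it does not measure miR-M1-7-5p and no value is given for it.

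Counts of mouse miRNAs, of unmatched families and of other small RNA genes were each tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, robust fit, filterByExpr, Benjamini-Hochberg adjusted p threshold 0.05). Infected was set against mock over all 5 libraries with no covariate. TMM factors were used for the mouse miRNAs and the other small RNAs. The total of all tags was the library size for the unmatched families, set before the data were examined in the expectation that most would occur in 1 group. That expectation was not met, since 2677 of the 2818 tested families had reads in both groups. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) where at least 3 members were tested. Shares of length, first base and annotation class were compared with a two-sided exact permutation test over the 10 splits, for which the smallest p is 0.1. DESeq2 1.42.0 was an alternative, beside other scalings, filters, match rules and the omission of each library. Tag matching and the remaining statistics used Python 3.11.15 with scipy 1.17.1.

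The named mouse miRNAs are the 10 most abundant, the 5 of smallest p in each direction (because fewer than 5 passed the threshold) and up to 4 of highest abundance per list. The rule also names up to 12 rising and 12 falling miRNAs past the threshold with a mean of at least 50 CPM and no overlap between groups. The named families are the 10 most abundant past the threshold. For other small RNAs the rule takes up to 5 per direction past the threshold at 50 CPM or more. Any other name is said to have been chosen after its values were seen.

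Each test was run once on simulated data with the libraries' own means, sizes and dispersions. The miRNA test of 264 features recovered 35.7% of 4-fold (5 of 14), 61.5% of 8-fold (8 of 13) and 84.6% of 32-fold changes (11 of 13). The test of 2818 unmatched families recovered 31.3% of 8-fold (21 of 67), 82.1% of 32-fold (55 of 67) and 98.5% of 256-fold changes (65 of 66). The test of 177 other small RNAs recovered 30% of 4-fold (3 of 10), 80% of 8-fold (8 of 10) and 100% of 32-fold changes (10 of 10). Among the unchanged features of the same simulations, the tests called 3 of 224 miRNAs, 8 of 2618 families and 2 of 147 other small RNAs. The changed features loosen the threshold, which raises both recovery and such calls, so recovery may be lower in data with few changes. The changes were rises and falls on randomly drawn features, so recovery need not hold for features nearly absent from mock. In the real data miR-M1-8, miR-M1-4 and miR-M1-9 had fitted log2 fold changes of 11.5, 10.8 and 9.82 and did not pass. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Chi-square values per degree of freedom between libraries of the same group lay between 628 and 2818, above counting error alone, so no library was a mere re-run of another. These values do not show that the libraries came from separate cultures.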

Results

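The series profiled small RNAs during lytic infection of a mouse fibroblast line with MHV68, a gammaherpesvirus of rodents that encodes its own miRNAs. Its design text states an interest in noncanonical miRNAs and endogenous siRNAs. The 3 infected libraries held 1843676, 5694227 and 8526798 reads and the 2 mock libraries held 5682600 and 6521133. Infected replicate 1 was the shallowest. Annotated mouse miRNA precursors took 63.6%, 69.9% and 70.3% of reads in the infected libraries and 70.2% and 69.4% in the mock libraries. Mir21a, Mir378a/Mir378b/Mir378c, Mir196a-1/Mir196a-2 and Mir143 were the most abundant mouse miRNAs. On the first scaling axis of the mouse miRNAs (56.9%) all infected libraries (1.13, 0.085 and -0.060) lay above both mock libraries (-0.28 and -0.88). Infected replicate 1 (1.13) and mock replicate 2 (-0.88) lay at its ends. The treatments did not form separate clusters, since infected replicate 3 correlated more with mock replicate 1 (0.985) than with infected replicate 2 (0.969).

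Viral miRNAs were present in all 3 infected libraries and nearly absent from mock. In infected cells 9 listed MHV68 miRNAs had reads, and together they took 2621, 6100 and 19265 CPM in infected replicates 1 to 3 against 5.28 and 0.153 in mock. miR-M1-8 stood at 2556 ± 3099 CPM (SD, n = 3), with 10 and 0 reads in mock and a pooled ratio of 4506 (95% counting interval 2450 to 9397). The spread between infected libraries was wide, with 6113 CPM of miR-M1-8 in replicate 3 against 431 in replicate 1.

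miR-M1-1, at 209 ± 49.6 CPM (SD, n = 3), had no mock read, and its infected reads pooled over libraries (224 CPM) were at least 913-fold above the floor of 3 counts over the mock group. The ratios and bounds of the other listed miRNAs are pooled in the same way and weigh the deeper libraries more. miR-M1-3 stood at 143 ± 75.1 and miR-M1-6 at 126 ± 111 CPM (SD, n = 3), each with 1 read in mock 1 and pooled ratios of 1427 (interval 255.9 to 56410) and 1945 (interval 348.9 to 76870). miR-M1-7-3p (46.5 ± 11.2 CPM, SD, n = 3) and miR-M1-4 (39.1 ± 32.1) had no mock read and pooled levels of 49.55 and 50.8 CPM, at least 202-fold and 207-fold above the floor, with 4 reads of miR-M1-4 in infected replicate 1. miR-M1-9 (19.97 ± 16.3) and miR-M1-2 (2.70 ± 2.82) had pooled levels of 23.8 and 3.86 CPM and bounds of 96.98-fold and 15.7-fold, with 321 of 383 reads of miR-M1-9 in infected replicate 3 and no read of miR-M1-2 in infected replicate 1. Without infected replicate 3 the ratio of miR-M1-8 was 1165 and that of miR-M1-6 was 652, and the bounds of miR-M1-9 and miR-M1-2 were 33.46-fold and 7.56-fold. Without mock replicate 1 no mock read of any of these miRNAs remained, and the bounds were 8026-fold for miR-M1-8, 488-fold for miR-M1-1, 254-fold for miR-M1-3, 346.5-fold for miR-M1-6, 108-fold for miR-M1-7-3p, 110.4-fold for miR-M1-4, 51.8-fold for miR-M1-9 and 8.39-fold for miR-M1-2. Without mock replicate 2 the ratios of miR-M1-8, miR-M1-3 and miR-M1-6 were 2098, 665 and 906, and the bounds were 425-fold for miR-M1-1, 93.9-fold for miR-M1-7-3p, 96.2-fold for miR-M1-4, 45.2-fold for miR-M1-9 and 7.31-fold for miR-M1-2. The most abundant tag of miR-M1-8 was CACTCACTGGGGGTTTGGTCAGG, which begins 2 nt inside the listed sequence. No tag of a listed miRNA matched a mouse transcript.

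**Figure D1:**
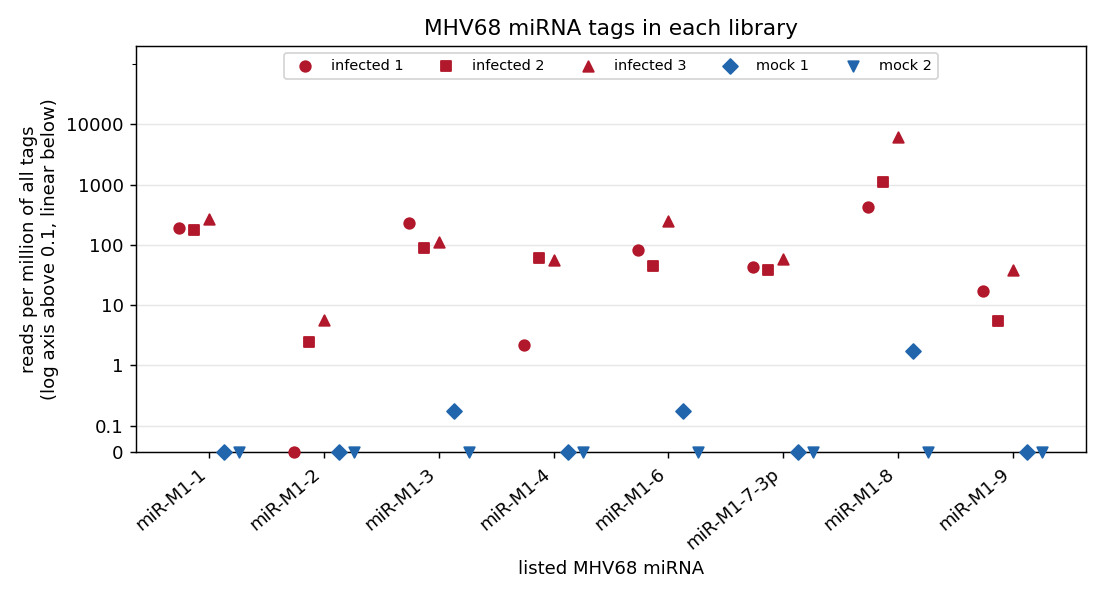
CPM of all tags (log axis above 0.1, linear below) for the listed MHV68 miRNAs reported here, with 1 point per library, infected in red and mock in blue. The miR-M1-8 points of the infected libraries lie between 431 and 6113 and those of mock at 1.76 and 0.

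In the edgeR quasi-likelihood test over all unmatched features, miR-M1-1, miR-M1-3, miR-M1-6 and miR-M1-7-3p rose, with adjusted p from 0.0210 for miR-M1-1 to 0.0393 for miR-M1-6 and miR-M1-7-3p. miR-M1-8 and miR-M1-9 (adjusted p = 0.0551 for both), miR-M1-4 (0.0740) and miR-M1-2 (0.201) did not pass, and all 9 passed when adjusted over the list alone. No listed miRNA passed without infected replicate 1, without infected replicate 2, without infected replicate 3 or without mock replicate 2, and 7 passed without mock replicate 1, while the read counts above come from every library.

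Of 2818 tested families of tags with no mouse match, those of listed miRNAs included, 30 rose in infected cells and 0 fell. At an unadjusted p under 0.05 in edgeR 227 were higher and 111 lower. The called families held 0.280%, 0.609% and 1.53% of reads in infected replicates 1 to 3, and at most 0.000528% in a mock library. Of the 30, 6 held tags of 5 of the listed MHV68 miRNAs, 2 lay 1 mismatch from a listed miRNA, and 22 had neither relation. The 6 families held most of the called reads in every infected library, so the shares above are mostly those of listed miRNAs. Families with at least 10 reads in every infected library and none in either mock library numbered 30, against 0 for the opposite pattern. These are not the same 30 families, since 20 of the called ones had no mock read.

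The 10 most abundant called families included those of miR-M1-1, miR-M1-3 and miR-M1-6, and 6 had no listed name. The family of CCCGTTCTGGATGCTGTGGGACA reached 248 ± 185 CPM (SD, n = 3) with 2 and 0 mock reads. TGGGAAGAGTCTGTTGAGTGGC reached 214 ± 114 with no mock read, and ACTGGACGGACCTCTGCTG reached 209 ± 219 with 2 and 0. AGCGAACCTCTGCTCACTGCCC stood at 138 ± 119 with no mock read, TATCTCATGTGAGCTCTTCTTTAT at 65.6 ± 31.4 with 1, and TCGGGGTAGCTCAATTGGTAGAGCAGCAGG at 63.4 ± 39.5 with 2. No MHV68 sequence was used, so these 6 families were not placed on a genome. The count of calls was unstable: 0 families passed without infected replicate 1, without infected replicate 2, without infected replicate 3 or without mock replicate 2, and 324 (55 higher, 269 lower) without mock replicate 1. DESeq2 called 194 (160 higher, 34 lower), single tags gave 125, mouse miRNA scaling gave 3, and 0 passed without a low count filter or with 3′ tailed mouse tags kept, the last an alternative chosen after seeing the data.

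Among mouse miRNAs, the lowest p values belonged to Mir378a/Mir378b/Mir378c, Mir142 and Mir182, and no miRNA passed the threshold. Mir378a/Mir378b/Mir378c, a family whose Mir378a lies in an intron of Ppargc1b (chromosome 18, 61397835 to 61397900, minus strand, GRCm38), stood at 37827 ± 13105 CPM in infected (SD, n = 3) and 187846 ± 129465 in mock (SD, n = 2). Its log2 fold change was -2.31 (SE 0.53; edgeR adjusted p = 0.139), with infected below mock in every library. Mir142, a miRNA of blood cells in an intron of Mir142hg (chromosome 11, 87756864 to 87756927, plus strand), had 46, 118 and 17 reads in infected and 4 and 1 in mock, a log2 fold change of 4.92 (SE 1.30; edgeR adjusted p = 0.180).

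Other miRNAs of low p and higher in every infected than mock library were Mir19b-1/Mir19b-2 (log2 2.83, SE 0.92), Mir19a (2.70, SE 0.95), Mir34b (2.41, SE 0.95) and Mir1a-1/Mir1a-2 (2.23, SE 0.88). Lower in every infected library were Mir182 (log2 -1.95, SE 0.52), Mir148a (-1.60, SE 0.53), Mir10b (-1.71, SE 0.57) and Mir598 (-2.47, SE 0.84). Mir142, Mir19a, Mir19b-1/Mir19b-2 and Mir34b were highest in infected replicate 1 and lowest in mock replicate 2, and Mir378a/Mir378b/Mir378c, Mir182, Mir148a, Mir10b and Mir598 ran the opposite way, along the first scaling axis. Mir19a and Mir19b-1 lie in exons of the Mir17hg transcript on chromosome 14, and Mir10b in introns of Hoxd3 and Hoxd4 on chromosome 2. Mir148a stood at 9091 ± 3656 CPM in infected (SD, n = 3) and 27528 ± 2834 in mock (SD, n = 2), and Mir10b at 5867 ± 3021 and 19178 ± 7412.

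Of the most abundant miRNAs, Mir21a, which lies in an exon of Vmp1 (chromosome 11), stood at 246974 ± 64209 CPM in infected (SD, n = 3) and 167808 ± 71558 in mock (SD, n = 2), with overlapping groups. Mir143 stood at 36495 ± 14207 and 90421 ± 4237 CPM and Mir99b at 31788 ± 16583 and 63603 ± 18337, both lower in every infected library. Mir196a-1/Mir196a-2, Mirlet7c-1/Mirlet7c-2 and Mirlet7f-1/Mirlet7f-2 had overlapping groups and log2 fold changes of 0.36, 0.19 and 0.39. Mirlet7a-1/Mirlet7a-2 (log2 0.51, SE 0.49) and Mir30a (-0.54, SE 0.50) did not overlap between groups. The small values of Mir196a and the let-7 members changed sign with upper quartile factors or GC correction, and Mir21a, Mir196a and Mirlet7f did so without mock replicate 2.

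**Figure D2:**
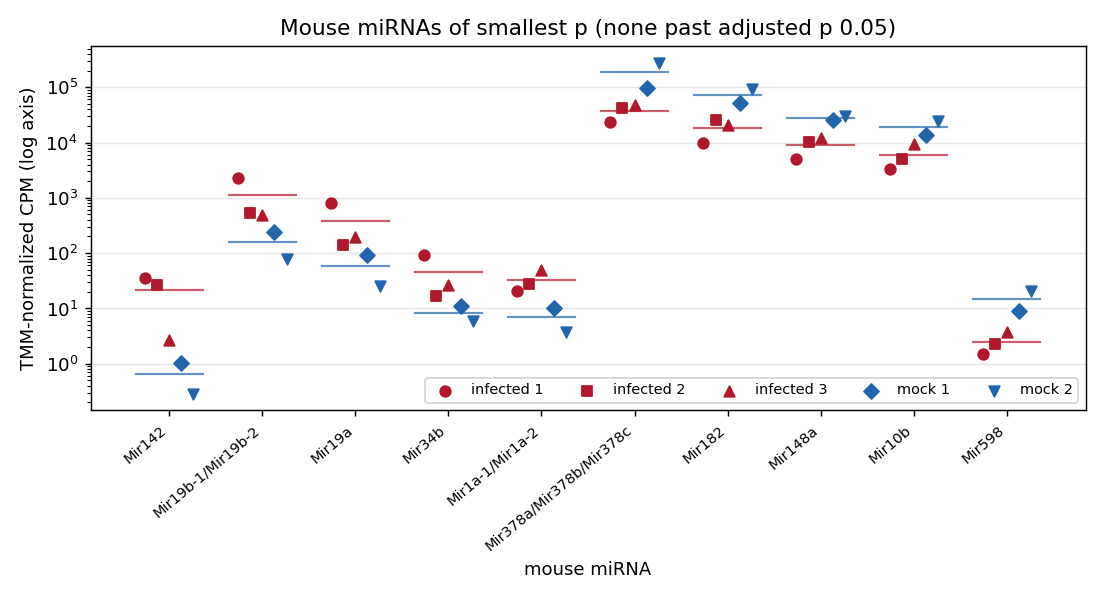
TMM-normalized CPM (log axis) of the 5 higher and 5 lower mouse miRNAs of smallest p, with 1 point per library and lines at the group means, infected in red and mock in blue. Mir142 spans 2.64 to 35.0 CPM in infected libraries, above 1.04 and 0.286 in mock, and Mir378a/Mir378b/Mir378c spans 23254 to 48644 CPM, below both mock libraries.

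Across the 264 miRNAs tested with edgeR, 0 passed, 25 had an unadjusted p under 0.05 (10 higher, 15 lower) and DESeq2 called 2, Mir142 higher and Mir378a/Mir378b/Mir378c lower. All infected libraries lay above mock for 50 miRNAs (18.9%) and below for 33 (12.5%), where chance gives 10% each way on average. The miRNAs are not independent, so a share can lie away from 10% by chance and these shares do not test for an effect of infection. Without infected replicate 3, 8 passed, 4 of them higher (Mir142, Mir19a, Mir19b-1/Mir19b-2, Mir29b-1/Mir29b-2) and 4 lower (Mir378a/Mir378b/Mir378c, Mir378d, Mir5114, Mir878), of which Mir29b, Mir378d, Mir5114 and Mir878 are named after their values were seen. The median log2 fold change was 0.08 with TMM, 0.41 with the size of all tags and -0.26 with upper quartile factors.

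Members of the miR-17-92 cluster and its paralogs, known for promoting cell proliferation, had more members higher than lower in infected cells without passing the test. Of 10 tested members 8 were higher in sign, 6 in every infected library, and camera gave an adjusted p of 0.0716 (0.646 with an estimated correlation). Mir20a stood at 6380 ± 2053 CPM in infected (SD, n = 3) and 2018 ± 1480 in mock (SD, n = 2), Mir17 at 4215 ± 259 and 2503 ± 178, and Mir92-1 at 3761 ± 1671 and 2979 ± 290. Mir20a, Mir19a and Mir19b-1/Mir19b-2 were highest in infected replicate 1 and lowest in mock replicate 2, the libraries at the ends of the first scaling axis. Mir93 stood at 14036 ± 6491 and 16040 ± 3533, and turned higher with the size of all tags. Without infected replicate 1 the camera adjusted p at the preset correlation was 0.00744, the one list call in any setting run. Settings that left out a library were not run with an estimated correlation.

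All 5 tested members of the miR-23-27-24 clusters were higher in sign (camera adjusted p = 0.178), with Mir27a at 5895 ± 2454 CPM in infected (SD, n = 3) and 2677 ± 179 in mock (SD, n = 2), Mir24-1/Mir24-2 at 4614 ± 1932 and 2359 ± 488, Mir23a at 616 ± 283 and 275 ± 1.72, and Mir27b at 5183 ± 1654 and 4375 ± 950, of which Mir27b turned lower with upper quartile factors. Mir27a, Mir24-1/Mir24-2 and Mir23a were also highest in infected replicate 1 and lowest in mock replicate 2. Of the miR-29 and miR-30 families 7 of 8 were higher in sign (adjusted p = 0.178), 5 of 8 with upper quartile factors, with Mir29a at 6127 ± 3197 and 3957 ± 1221 CPM. Mir30e (log2 0.36, SE 0.52) and Mir30d (0.23, SE 0.58) turned lower with upper quartile factors. The let-7 family, known for restraining proliferation, had 7 of 9 members higher (adjusted p = 0.588) and 3 of 9 with upper quartile factors or GC correction. Mirlet7b had a log2 fold change of 0.03 (SE 0.51) and turned lower with DESeq2 size factors or upper quartile factors. Among the miR-34 and p53 responsive miRNAs 4 of 5 were higher (adjusted p = 0.531), with Mir34c at 3650 ± 1178 and 2641 ± 10.98 CPM, Mir192 at 599 ± 289 and 875 ± 169, and Mir194-1/Mir194-2 at 93.7 ± 34.9 and 50.7 ± 23.6.

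Of the inflammation and NF-kB responsive miRNAs 4 of 7 were higher in sign (camera adjusted p = 0.588), 6 of 7 with the size of all tags and 5 of 7 with GC correction. Mir155, which is induced in activated immune cells, stood at 1350 ± 878 CPM in infected (SD, n = 3) and 459 ± 184 in mock (SD, n = 2), and Mir146b at 1500 ± 660 and 1556 ± 999, which turned higher with the size of all tags. Mir9-1/Mir9-2/Mir9-3 stood at 96.4 ± 41.5 and 294 ± 1.94 CPM. Fibroblast and mesenchymal miRNAs were lower for 8 of 13 (adjusted p = 0.588), with Mir125b-1/Mir125b-2 at 9530 ± 2840 and 13878 ± 9866 CPM and Mir199a-1/Mir199a-2/Mir199b at 8839 ± 1618 and 6364 ± 1580. Of the noncanonical group, miRNAs that derive from introns, snoRNAs or short hairpins, 2 of 6 were higher (adjusted p = 0.873), 4 of 6 with the size of all tags, 3 of 6 with GC correction and 1 of 6 with upper quartile factors. Mir320 stood at 361 ± 156 and 752 ± 853 CPM, Mir1839 at 361 ± 61.8 and 589 ± 50.9, and Mir484 at 61.3 ± 18.1 and 20.7 ± 9.50. Mir1981 (log2 0.27, SE 0.64) turned lower with upper quartile factors. The Dlk1-Dio3 cluster had 7 of 10 members higher (adjusted p = 0.873), 4 of 10 with upper quartile factors, with Mir134 at 56.7 ± 8.63 and 140 ± 36.2 CPM and Mir379 at 199 ± 43.3 and 274 ± 192. Mir541 (log2 0.53, SE 0.76) turned lower with upper quartile factors, and Mir127 (1.72, SE 1.41) overlapped between groups.

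Because the labels also name macrophages, markers of other cell types were measured. Of 3 tested haematopoietic and macrophage miRNAs 2 were higher in sign (adjusted p = 0.394), and 1, Mir142, passed when adjusted over the list alone. Mir342 stood at 216 ± 61.4 CPM in infected (SD, n = 3) and 108 ± 10.8 in mock (SD, n = 2), and Mir3107/Mir486 at 31.96 ± 20.7 and 53.3 ± 12.3. The myeloid miRNAs Mir223 and Mir511 had no read among 11146690 infected and 8510441 mock miRNA reads, which allows up to 0.153 CPM. Neuronal miRNAs were low, with 1 of 3 higher (camera adjusted p = 0.588): Mir128-1/Mir128-2 at log2 -1.20 (SE 0.77), Mir129-1/Mir129-2 at -1.05 (SE 0.86) and Mir138-1/Mir138-2 at 1.22 (SE 0.86). Lists with fewer than 3 tested members had no set test. The muscle list had Mir206 at 4547 ± 1629 and 6729 ± 689 CPM and Mir1a-1/Mir1a-2 at 32.3 ± 14.8 and 6.91 ± 4.52, the latter passing when adjusted over the list alone. Epithelial Mir203 stood at 9.52 ± 10.3 and 29.5 ± 9.15 CPM, Mir200c at 3.25 ± 2.42 and 4.77 ± 4.56, liver Mir122 at 4.02 ± 1.77 and 1.74 ± 0.840, and embryonic stem cell miRNAs had no reads. Over 11 lists 0 passed with camera or fry, and 3 had an unadjusted camera p under 0.05.

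Among other small RNAs, fragments of 2 snoRNAs fell in infected cells. Snora62, a box H/ACA snoRNA in an intron of the ribosomal protein gene Rpsa (chromosome 9, 120130415 to 120130563, plus strand, GRCm38), had 2, 14 and 14 reads in infected and 136 and 311 in mock, a log2 fold change of -4.11 (SE 0.62; edgeR adjusted p = 0.0340). Gm26247, annotated as a snoRNA over an exon of 2410002F23Rik (chromosome 7, 44248090 to 44248180, plus strand), had 11, 85 and 111 reads in infected and 606 and 592 in mock, a log2 fold change of -2.87 (SE 0.40; edgeR adjusted p = 0.0340). Both were lower in all 3 infected libraries than in either mock library.

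Of 177 other small RNAs tested with edgeR, 0 rose and 2 fell, 8 were higher and 15 lower at an unadjusted p under 0.05, and DESeq2 called 3, all lower. Snord49a (log2 -1.83, SE 0.36; edgeR adjusted p = 0.0970) and the Y RNA Rny3 (-1.16, SE 0.35; edgeR adjusted p = 0.238), named after their values were seen, were lower without passing. Both calls ended without infected replicate 2, without infected replicate 3, without mock replicate 1 or without mock replicate 2, each of which gave 0 calls.

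Several shares of length and first base did not overlap between the groups, and none could pass the test with 3 against 2 libraries. Tags of 23 nt, the length of the most abundant Mir21a tag, took 31.9%, 26.0% and 27.0% of infected and 22.7% and 20.5% of mock reads. Tags of 20 nt, the length of the main Mir143 tag, took 4.03%, 5.29% and 6.51% against 8.62% and 7.40%. Reads beginning with A, as the main Mir378a/Mir378b/Mir378c tag does, took 10.2%, 12.8% and 13.7% against 15.0% and 26.9%. With Mir21a, Mir143 and Mir378a/Mir378b/Mir378c left out, the share beginning with U was 68.7%, 64.4% and 65.3% in infected and 66.5% and 59.1% in mock, and the groups overlapped for U, for A and for 23 nt, while 20 nt stayed lower and 22 nt, lower with all tags, turned higher.

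**Figure D3:**
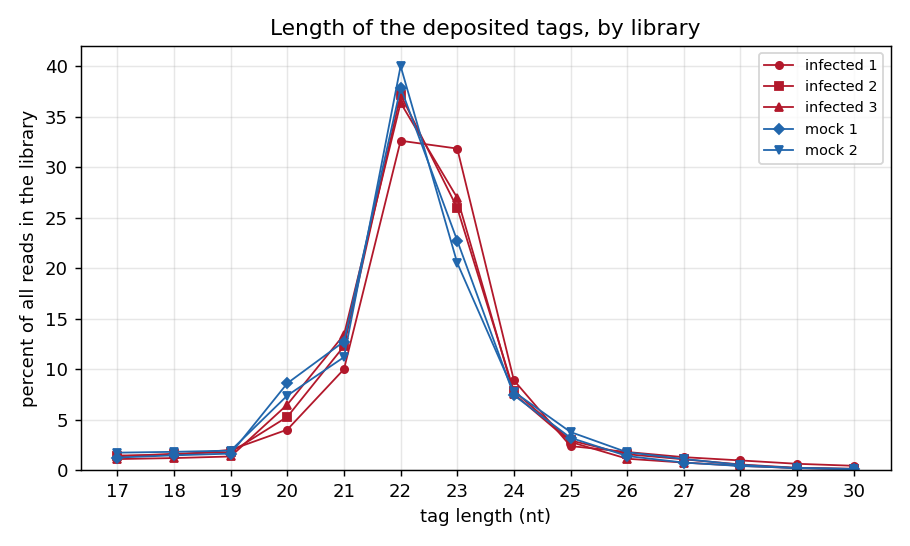
Percent of all reads (vertical axis) at each tag length in nt (horizontal axis), with 1 line per library, infected in red and mock in blue. At 23 nt the infected libraries lie between 26.0% and 31.9% and the mock libraries at 22.7% and 20.5%.

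Unmatched tags took 9.76%, 10.2% and 10.1% of infected and 7.98% and 9.54% of mock reads, while fragments of mRNA or long RNA took 0.633%, 0.929% and 0.719% against 1.13% and 1.76%. In 10 of 30 shares the groups did not overlap (33.3%, where chance gives 20%), 3 higher and 7 lower in infected. The shares are not independent, and tags of 17 nt enter both as a length and as a class, so this count tests nothing. With 3 against 2 libraries the smallest two-sided exact permutation p is 0.1, so no share could pass. Without mock replicate 1, 19 shares did not overlap. Groups with fewer libraries fail to overlap more often by chance, so the 19 cannot be set directly against the 10. With tags seen at least 5 times the unmatched, mRNA or long RNA and U shares overlapped. With each distinct tag counted once 7 of 30 shares did not overlap, with 17 nt among them under both entries, and the unmatched, 23 nt, U and A shares overlapped.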

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

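The GC correction, the counts by precursor arm and by most frequent start, and the retention of 3′ tailed tags among unmatched families were chosen after seeing the data. For the listed MHV68 miRNAs alone, so were the omission of libraries (test, ratios and bounds) and the block; where run for other results they were planned. Restricting miRNA tags to an exact annotated mature start was not run, since mature positions were not used. Leaving out each library in turn gave 0 to 8 calls among mouse miRNAs (0 with all libraries), 0 to 324 among unmatched families (30), 0 to 7 among listed MHV68 miRNAs (5), 0 to 2 among other small RNAs (2), 0 to 1 among lists (0) and 11 to 19 shares without overlap (10); fits with 1 mock library take its spread from the infected ones. Shares without overlap are more frequent by chance with fewer libraries, so the 11 to 19 cannot be set directly against the 10. Infected and mock libraries share numbers 1 and 2, with correlations of deviations of 0.151 and 0.429, but no stated common origin, so whether the numbers pair them is unknown. With the replicate block, which also leaves out infected replicate 3, the calls were 8, 51, 8 and 0 for mouse miRNAs, unmatched families, listed MHV68 miRNAs and other small RNAs, against 8, 0, 0 and 0 without that library alone. Mouse miRNA calls were 1 with no low count filter, 5 with at least 50 counts in 2 libraries, 2 with DESeq2 and 1 with the most frequent start only. They stayed at 0 with DESeq2 size factors, all-tag size, upper quartile factors, single precursors, tailed tags, arms and GC correction. Family calls were 0 with no filter, 37 with at least 50 counts in 2 libraries, 194 with DESeq2, 3 with mouse miRNA scaling, 125 for single tags and 0 with tailed tags kept. Among the mouse miRNAs named for abundance or p, signs reversed for Mir21a without mock replicate 2 (-0.0368; -0.0368 to 1.11 over omitted libraries), Mir196a without mock replicate 2 (-0.217; -0.217 to 0.962) and with upper quartile factors (-0.0398), Mirlet7c with upper quartile factors (-0.16) and GC correction (-0.0629), Mirlet7f without mock replicate 2 (-0.124; -0.124 to 0.798), with upper quartile factors (-0.0948) and GC correction (-0.37), and Mirlet7a with GC correction (-0.0383). The cause of these changes was not tested, apart from the fewer libraries in the fits that leave one out. Over the 18 mouse miRNAs named for abundance or p, 252 other values kept direction and side of the threshold and 18 passed it; over named families 58 lost the call and 52 kept it. Other list members were followed under scalings only.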

Other observations

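The GC correction, the GC correlations, the spread of viral reads in mock, the tests on tag families and the tests of Mir142 were chosen after these patterns were seen; the tests of Mir142 were written down before their own values were seen.

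Several unmatched families that rose in infected cells overlapped one another. TGGCACAGAATGGATCAC, ACAGAATGGATCACAGAA and TGGATCACAGAAAAGGTGC overlapped by 14 and 12 nt, TCGCTACTGGACGGACCT and ACTGGACGGACCTCTGCTG by 13 nt, and TAAGATTACTGTTGGGATATCGCGC ended in 10 nt that begin miR-M1-7-3p. Of the 30 called families 11 overlapped another by at least 9 nt, against a median of 0 and a highest value of 7 in 1000 draws of 30 other families. This count is of the overlaps that prompted it, so it does not test whether the families are pieces of the same transcripts. The family of TCGGGGTAGCTCAATTGGTAGAGCAGCAGG holds the eukaryotic tRNA A box consensus, and CAATTGGTAGAGCAGCAGG lies inside it. MHV68 is known to encode tRNA-like transcripts, which could be a source of such tags. The consensus occurred in 1 of 30 called and 53 of 2788 other families (Fisher's exact p = 0.44, two-sided), so the test left this open with so few tags holding it. Nor could the test decide with more tags. Mouse tRNA tags remain among the other families and may hold the consensus, and pieces from outside the A box cannot hold it.

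Mir142 was higher in infected libraries, with 181 reads against 5, without passing the test (edgeR adjusted p = 0.180). Macrophage RNA may be a source because the labels name macrophages, though they do so for every sample, mock included. The pooled reads of Mir223, Mir511, Mir150, Mir451a and Mir144 numbered 5 in infected and 1 in mock, a ratio of 3.82 with an exact interval of 0.427 to 181, which spans both no change and the 5-fold rise set as the mark of that source. The pooled reads were all of Mir150 (1 infected, 1 mock), Mir451a (1 and 0) and Mir144 (3 and 0), too few for the ratio to decide. The myeloid miRNAs Mir223 and Mir511 had no reads in any library, so the ratio holds none of theirs and neither gave a sign of macrophage RNA. A GC bias shared by miRNAs of like GC content is argued against as the whole cause. The log2 fold change after correction was 4.51 (SE 1.19) against 4.92 (SE 1.30) before. The correction removes only a smooth trend with GC content, so it does not address a bias particular to the Mir142 tag. Over infected replicates 1 to 3 Mir142 stood at 35.0, 26.8 and 2.64 CPM (TMM-normalized), while listed viral miRNAs took 2621, 6100 and 19265 CPM of all tags. Mir142 thus did not follow the viral reads across these libraries. Induction by infection was not tested separately and stays open.

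AU-rich mouse miRNAs tended higher in infected libraries, with a rank correlation across 264 miRNAs of -0.23 between tag GC content and log2 ratio; miRNAs are not independent replicates. The median log2 ratio was 0.52 below 40% GC, 0.20 from 40%, -0.34 from 50% and 0.00 from 60%, so the most GC-rich miRNAs were not lower. A GC bias between libraries is a candidate explanation, since the mock libraries, which share a treatment, gave -0.47 between themselves. Infection as the cause was left undecided, as 4 of 6 pairs of an infected with a mock library lay below -0.1. Over mock replicate 2 infected replicates 1 to 3 gave -0.34, -0.26 and -0.38, and over mock replicate 1 -0.11, 0.26 and 0.07. The trend therefore rested mostly on mock replicate 2. The 6 pairs replaced a test on infected replicates 2 and 3 over mock replicate 1, because it rested on 1 mock library. Its value of 0.21 had been seen and spoke against infection. After GC correction Mir378a/Mir378b/Mir378c had a log2 fold change of -1.97 (SE 0.43; edgeR adjusted p = 0.0525) against -2.31 (SE 0.53) before.

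Listed viral miRNAs had 30 reads in mock replicate 1 and 1 in mock replicate 2. Carry-over of reads from infected libraries and infection of a small part of the mock cells both predict that these reads spread over the viral miRNAs as in infected cells. Among them mock replicate 1 had 10 reads of miR-M1-8 and 1 each of miR-M1-3 and miR-M1-6, where the infected shares predict 8.73, 0.277 and 0.377. An exact multinomial test of these 30 reads gave p = 0.413. The test may therefore be met by either explanation and does not separate them.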
